A study of Synechocystis sp. PCC 6803 with 12 samples.

How the data were processed

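Gene expression was measured in Synechocystis sp. PCC 6803 on 12 arrays of a custom Agilent design, in 4 groups of 3 arrays (control, dark, high light and CO2 depletion). Per the labels, cells were collected by rapid filtration, RNA was extracted with TRIzol, and 2 µg of total RNA was labelled directly with the dye Cy3, without cDNA synthesis. Each of 3 slides held 4 arrays, 1 of every group. Per the file headers, the authors' scans were quantified with Feature Extraction 10.5.1.1, and each file holds processed and raw signal as intensity. The processed signal is background-subtracted and detrended within the array but not scaled between arrays. Per the file headers, other columns hold flags of 0 or 1 for spots that are well above background, saturated or outliers. The deposited value table of the series holds intensity on which the authors made the arrays comparable, with column medians that nearly coincide, and its entries were matched to the probes by their order. Its spots ranked as the raw median signal did on every array (rank correlation 1). Its medians were 2481.6 to 2482.9, against 305 to 1930 for the processed signal. Background was therefore apparently not subtracted in it, and background left in narrows folds. The submitters name limma for their own processing, without a version.

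The design has 40862 spots other than controls, 2 for each of 20431 probes of 45 to 60 nt. Probes were classed from the annotation in the scanner files as genes (16999 probes, 3518 genes), antisense segments (1879 probes, 1111 segments), intergenic segments (1344 probes, 897 segments), CRISPR (138 probes) and rRNA (22 probes), and 49 probes were left out because they had no class. The files name no genome build, and coordinates are those of the design. Symbols come from the fixed gene lists or, for genes outside them, from the same annotation. None of the locus tags was found in the separate table of reference symbols (0 matched), which was not used.

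The log2 processed signal of each spot was taken relative to the 75th percentile of the non-control spots of its array, and spots were averaged to probes, leaving out spots with an outlier flag and keeping saturated ones. Probes were averaged to genes or segments, with a median of 5 probes per gene. A gene or segment was tested when at least 1 of its probes was well above background on all 3 arrays of at least 1 group. Linear models over the 12 arrays were fitted with limma 3.58.1 in R 4.3.3 (files were read with the package data.table, version 1.17.8), and variances were moderated with eBayes (prior degrees of freedom 3.86, residual degrees of freedom 8). All tests are 2-sided. Adjusted p-values follow Benjamini and Hochberg, within genes, antisense or intergenic segments and for each comparison. A gene was called with an adjusted p under 0.05 and a fold of at least 2. Where any probe of a gene was not well above background on all arrays of the dimmer group, its change is given as a lower bound on the fold. The bound sets the mean of the brighter group against that of the dimmer group, with each probe not above background on an array at the lowest signal well above background on it, or at its own signal if that is higher. No fold is given where the bound is under 1 or no probe was above background in the brighter group, and such genes count as 0 in list medians at bounds. The number of arrays limits the precision, and only 3 per group were made.

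The comparisons were dark, high light and CO2 depletion against control, and high light against dark. The 27 gene lists, the comparisons, the alternatives and the rule for naming genes were fixed before the data were examined. Lists were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with the rotation test fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes. Changes of genes and of the antisense segments opposite to them were correlated with Spearman's rho over 754 pairs, with 9999 permutations, and 3 such relations were adjusted together. Shared genes were set against independent lists and against 100 simulated draws without change that keep the same controls. Named genes were the 8 largest rises and 8 largest falls of each comparison whose arrays were separated and whose probes all went the same way, up to 3 members of each list, 14 fixed genes, and 4 rises and 4 falls among antisense and intergenic segments, and genes outside the rule are said to have been named after their values were seen. Some members that the rule gives are not written out in the text, but all of them are in the counts of how values depend on the processing.

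Alternatives were quantile normalization, no scaling, normexp background correction with an offset of 50, the deposited value table, no filter on dim probes, a probe above background on all 12 arrays, the median over probes, the slide as a block, no minimum fold, an adjusted p under 0.01, a prior with trend and robust variances, adjustment over all classes, only the arrays compared, Pearson's r, only changed pairs, and leaving out each array in turn. Chosen after seeing the data were scaling to spots above background on all arrays, a common floor after scaling, leaving out cross-hybridising probes, counting only calls above background in the brighter group, and counting only calls of at least 2-fold at their bound. The pipeline was tested on simulated data, with 50 genes each changed 3-fold and 2-fold. Of the genes changed 3-fold 50, 50 and 49 were called in the dark, high light and CO2 depletion settings, and of those changed 2-fold 27, 28 and 21.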

Results

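RNA levels were measured in the cyanobacterium Synechocystis sp. PCC 6803, a unicellular freshwater species that lives by photosynthesis, on 12 arrays of 1 custom design. The design carries probes for both strands of the chromosome and plasmids, so that protein-coding genes, the strand opposite to genes (antisense) and the stretches between genes (intergenic) were read in the same hybridisation. Total RNA was labelled directly, without copying into cDNA, which keeps the strand of origin. There were 4 groups of 3 arrays each. Control cultures grew at 50 µmol photons m-2 s-1, dark cultures were kept without light for 1 h, and high light cultures were moved to 500 µmol photons m-2 s-1 for 30 min. CO2 depletion cultures were spun down, washed and held for 6 h in medium of pH 7.0 without carbonate and without an air stream, so that this group also differed from the control in handling and pH. Labels did not say whether the 3 arrays of a group came from separate cultures, and p-values may therefore measure only the technical spread between arrays.

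Signal over background set the depth. Spots well above background made up 76.2 to 80.7% of the spots on control arrays, 43.1 to 52.6% on dark arrays, 80.0 to 92.5% on high light arrays and 68.8 to 81.7% on CO2 depletion arrays. Of 3518 genes, 3275 were above background on all control arrays, 2348 on all dark arrays, 3323 on all high light arrays and 3126 on all CO2 depletion arrays, and 3381 genes (96.1%) were so in at least 1 group and were tested. Each array was scaled to its 75th percentile, and changes are relative to that level. Without scaling, the median gene changed by -1.35 (log2) in the dark, by 0.92 in high light and by 0.08 under CO2 depletion against the control, and after scaling by -0.10, 0.18 and 0.03. Values after ± are standard errors of a log2 change in the limma fit (n = 3 arrays per group). That fit takes the variance of a gene over all groups. Standard errors and p-values can therefore hold spread from groups outside a comparison. In the dark comparison the standard error of cmpA was 1.462, with standard deviations of 0.225 (dark), 0.18 (control) and 4.342 (high light). That of nrtC was 0.306, with 0.088 (dark) and 0.114 (control). Genes with an adjusted p under 0.05 and a change of at least 2-fold are said to have risen or fallen. Coordinates are those of the array design and span the probes of a gene. Where a probe of a gene was not well above background in the dimmer group, the change is a lower bound, written as at least N-fold, with such probes at the lowest signal above background or at their own if that is higher. Values of such genes by slide, or without an array or setting, are fitted changes.

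The first comparison asked which transcripts changed after 1 h of darkness. In the dark, messages for the small heat shock protein HspA, for the chaperones DnaJ2 and ClpB1 and for the sigma factors SigB and SigH were higher, while most genes of the lists for ATP synthase, chlorophyll synthesis, the NDH-1 core, the Calvin cycle, nitrogen assimilation and ribosomal proteins fell. The gene hspA (sll1514, probes at 460280 to 460711 on the reverse strand of the chromosome) rose 787-fold (9.62 ± 0.18, adjusted p = 1.27e-12). The heat shock co-chaperone gene dnaJ2 (slr0093) was at least 22.76-fold higher and the disaggregase gene clpB1 (slr1641) rose by 3.89 ± 0.13. The gene cpcG2 (sll1471, reverse strand, 3403548 to 3404273), for a rod-core linker of the phycobilisome, the light-harvesting antenna, was at least 8.4-fold lower and not well above background in the dark. In all, 1449 of 3381 genes changed, of which 571 rose and 878 fell, and 390 of the falls were to and 10 of the rises from a level not well above background. Every probe was above background in the dimmer group for 84 of the falls and 218 of the rises, and 354 falls and 321 rises were at least 2-fold at their bound, a setting chosen after seeing the data. A further 73 genes that rose were not well above background on all dark arrays. The 3 dark and 3 control arrays did not overlap for 87.6% of genes, against 10% by chance.

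Other large rises in the dark were those of sll0846 (6.96 ± 0.11) and sll0572 (5.84 ± 0.10), both of unknown function. The carbamate kinase gene arcC (sll0573) was at least 50.97-fold higher, the hydrogenase maturation gene hypA (slr1675) at least 54.22-fold, the transposase gene ssr2227 at least 40.61-fold and the plasmid gene slr5037 on pSYSM at least 55.69-fold, and ssr2786 rose (5.64 ± 0.27). The water channel gene apqZ (slr2057) was at least 10.64-fold lower (adjusted p = 1.04e-11), ssl1046 at least 9.44-fold lower, and gyrB (sll2005), which encodes a subunit of DNA gyrase, was at least 4.78-fold lower. The light-repressed gene lrtA (sll0947) rose by 1.99 ± 0.12 and the RNA helicase gene crhR (slr0083) was at least 5.41-fold lower. The D1 protein genes psbA2 (slr1311) and psbA3 (sll1867), which share cross-hybridising probes, rose by 1.02 ± 0.10 each, just past the 2-fold limit. Without scaling both went down (-0.24 each), and under quantile normalization psbA2 stood at -0.07. Both also fell short of 2-fold without control replicate 3 (0.96 each) and without dark replicate 5 (0.96 each). The high-light-inducible gene hliA (0.34 ± 0.16), the photosystem I gene psaA (0.68 ± 0.22) and the phycocyanin gene cpcB (-0.80 ± 0.11) did not pass the threshold. The bicarbonate transporter gene cmpA was not well above background in either group and the flavodiiron gene flv4 not in the dark, and no fold is given for either.

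Of the 27 gene lists fixed before the data were examined, 11 were called against the other genes in the dark, 1 upward and 10 downward, in limma's camera test with its preset correlation of 0.01. Other groupings of the same 6 arrays gave up to 13 called lists, so that the number of calls does not set the real groups apart. None of the 11 held when the correlation between members was estimated from the data, and that second adjusted p is given beside each call. All counts of members in the gene lists were the same when adjusted over the list alone. Of 53 ribosomal protein genes 35 fell and none rose (adjusted p = 3.57e-07, and adjusted p = 0.2975 with an estimated correlation), with rps3 (sll1804) at least 8.19-fold lower and rpl2 (sll1802) at least 10.62-fold lower. All 9 ATP synthase genes fell (adjusted p = 1.44e-04, and adjusted p = 0.2975 with an estimated correlation), including atpG (sll1323, at least 13.49-fold lower) and atpD (sll1325, at least 9.51-fold lower). In chlorophyll and tetrapyrrole synthesis 13 of 16 genes fell (adjusted p = 9.91e-05, and adjusted p = 0.2975 with an estimated correlation), with chlP (sll1091), which makes the phytyl tail of chlorophyll, at least 17.52-fold lower. Of 13 core genes of the NDH-1 complex of respiratory and cyclic electron flow 10 fell (adjusted p = 0.002582, and adjusted p = 0.505 with an estimated correlation), and ndhG (sll0521) was at least 6.91-fold lower. Of 11 Calvin cycle genes 8 fell and 1 rose (adjusted p = 0.01076, and adjusted p = 0.3369 with an estimated correlation), among them the phosphoribulokinase gene prk (sll1525, at least 17.42-fold lower) and pgk (slr0394, at least 8.39-fold lower). Of 15 phycobilisome genes 8 fell (adjusted p = 0.01076, and adjusted p = 0.505 with an estimated correlation), including the allophycocyanin genes apcB (slr1986, -3.99 ± 0.18) and apcA (slr2067, -3.67 ± 0.13).

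Of 25 photosystem II genes 10 fell and 2 rose in the dark (adjusted p = 0.02056, and adjusted p = 0.4839 with an estimated correlation). The falls included psbO (sll0427), which encodes the manganese-stabilising protein, at -4.55 ± 0.13 and psbL (smr0007) at -3.09 ± 0.09, and the rises were psbA2 and psbA3. Of 10 genes for cytochrome b6f and electron carriers 6 fell (adjusted p = 0.02056, and adjusted p = 0.2975 with an estimated correlation), among them petH (slr1643, at least 9.06-fold lower) and petA (sll1317, at least 16.84-fold lower). Of 8 respiratory oxidase genes 6 fell (adjusted p = 0.02056, and adjusted p = 0.4839 with an estimated correlation), with ctaE1 (slr1138) at least 1.79-fold lower. Of 14 nitrogen assimilation genes 10 fell and 2 rose (adjusted p = 0.02892, and adjusted p = 0.505 with an estimated correlation). The nitrite reductase gene nirA (slr0898) was at least 6.63-fold lower and the nitrate transporter gene nrtC (sll1452) at least 12.61-fold lower. Its neighbour nrtB (sll1451) was at least 10.91-fold lower, and the glutamine synthetase gene glnA (slr1756) fell by 2.67 ± 0.32 on the log2 scale. The 2 rises were gifB (sll1515, 4.54 ± 0.11) and gifA (ssl1911, 3.48 ± 0.40), whose products are known as inactivating factors of glutamine synthetase, and both were named here after their values were seen. Of 314 plasmid genes 104 rose and 35 fell (adjusted p = 7.49e-06, and adjusted p = 0.2975 with an estimated correlation), with a mean change of 0.46 that turned to -0.80 without scaling, and the sulfide-quinone reductase gene sll5036 was at least 12.08-fold higher.

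The other lists were not called in the dark in the main fit, but several were under other settings. Photosystem I was called downward under quantile normalization (adjusted p = 0.003379, against 0.1198), with normexp (3.07e-04), in the value table (8.71e-04) and with a common floor (0.01701). Type IV pili was called downward under the same 4 settings (0.02362, 0.004406, 0.0127 and 0.024, against 0.08286) and without scaling (0.03585). Called upward were transposases without cross-hybridising probes (6.64e-04, against 0.1198), sigma factors with scaling to spots above background on all arrays (0.0206, against 0.07229) and, ranked above other genes while its mean was negative, chaperones and proteases without scaling (0.007329, against 0.2003). The floor, this scaling and the omission of cross-hybridising probes were chosen after seeing the data. Of 9 sigma factor genes 6 rose and 2 fell, with sigB (sll0306) at 3.27 ± 0.09, sigH (sll0856) at 2.69 ± 0.08 and the principal sigma factor gene sigA (slr0653) at least 7.29-fold lower. Of 24 chaperone and protease genes 7 rose and 5 fell. Mean changes of these lists were 0.90 and 0.79 and turned negative without scaling (-0.36 and -0.47). In carboxysome and RuBisCO 8 of 12 genes fell, including rbcL (slr0009, -2.26 ± 0.09) and the carboxysome gene ccmM (sll1031, at least 9.56-fold lower). The list passed without control replicate 2 (adjusted p = 0.04742, against 0.05464), without control replicate 3 (0.04932), without dark replicate 4 (0.04883) and without high light replicate 7 (0.04729), which is part of the same fit. It also passed under quantile normalization (0.01289), without scaling (0.03585), with normexp (4.56e-04), in the value table (0.009373), with the floor (0.004139) and without cross-hybridising probes (0.04952). Over all alternatives its adjusted p lay between 4.56e-04 and 0.07921. In inducible inorganic carbon uptake 8 of 14 fell, including the bicarbonate transporter genes sbtA (slr1512, at least 2.01-fold lower) and bicA (sll0834, at least 4.36-fold lower). Members that fell numbered 5 of 12 in photosystem I (psaE, ssr2831, -2.49 ± 0.12), 4 of 5 in bidirectional hydrogenase (hoxU, sll1223, at least 1.57-fold lower, and hoxH, too dim for a fold) and 4 of 10 in type IV pili (pilQ, slr1277, at least 6.71-fold lower). They numbered 5 of 10 in circadian clock (kaiC3, slr1942, at least 1.15-fold lower, and kaiB1 and kaiB2, too dim for a fold) and 1 of 5 in flavodiiron proteins (flv3, sll0550, at least 2.57-fold lower). No member of these 5 lists rose. The hydrogenase and clock genes named here were short of 2-fold with normexp, in the value table and with the floor. In sugar catabolism 6 of 14 fell and 1 rose, the fall of the glucose 6-phosphate dehydrogenase gene zwf (slr1843) being at least 1.68-fold and that of pfkA2 (sll0745), the rise, at least 1.81-fold. Among high-light-inducible and phycobilisome degradation genes 2 of 7 rose, nblB (slr1687, 2.04 ± 0.19) and nblA1 (ssl0452, 1.44 ± 0.25). Oxidative stress defence had 2 rises and 3 falls among 11 genes, with the orange carotenoid protein gene ocp (slr1963) at 3.49 ± 0.15 and gpx2 (slr1992) at least 1.97-fold lower. The other rise, sodB (slr1516, 1.23 ± 0.11), was -0.02 without scaling. Rises and falls numbered 2 and 1 of 8 in phosphate uptake, 1 and 1 of 6 in iron acquisition and storage, 1 and 1 of 3 among RNA helicase, RNA-binding and light-repressed genes and 22 and 18 of 98 among transposases. The phosphate rises were phoA (sll0654, at least 1.58-fold) and nucH (sll0656, at least 1.51-fold), and the iron genes were futA2 (slr0513, 1.16 ± 0.17) and bfrA (sll1341, at least 2.6-fold lower). Without scaling phoA, nucH and futA2 went down (-0.14, -0.18 and -0.10). Below 2-fold were also phoA without control replicate 3 (1.00) and nucH without dark replicate 6 (0.98). The mean change was above 0 in the flavodiiron list (0.33, median 0.87) while camera ranked it downward, and below 0 in the iron list (-0.06, median 0.20) while camera ranked it upward. For the iron and oxidative stress lists the rotation test fry gave the downward direction. Means that were above 0 and turned negative without scaling were those of the flavodiiron (-0.92), oxidative stress (0.20 to -1.05), phosphate (0.21 to -1.05), transposase (0.22 to -1.04) and high-light-inducible (0.63 to -0.62) lists. With changed genes at their bounds, and at 0 where no fold is given, list medians in the dark moved from -1.64 to 0.00 in hydrogenase, from -0.94 to -0.08 in the clock, from -1.49 to -0.29 in respiratory oxidases and from -1.55 to -0.65 in carbon uptake. They moved from -0.80 to -0.53 in sugar catabolism, from -3.03 to -1.96 in nitrogen assimilation, from -2.26 to -1.38 in chlorophyll synthesis and from 0.62 to 0.22 among plasmid genes. At least 2-fold at their bound were 0 of the 4 falls in hydrogenase, 0 of 5 in the clock, 0 of 6 in sugar catabolism, 1 of 6 in respiratory oxidases, 1 of 5 among chaperones, 9 of 13 in chlorophyll synthesis and 37 of the 104 plasmid rises.

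Rises and falls in the dark depended on the scaling, with 116 and 2041 genes without scaling, 281 and 1241 with scaling to spots above background on all arrays, a setting chosen after seeing the data, and 376 and 321 with normexp background correction. The number of changed genes ranged from 403 in the deposited value table to 2783 with no minimum fold, and with the slide as a block no gene or list named in the dark changed its call.

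The second comparison asked which transcripts changed after 30 min at 10 times the growth light. In high light, most genes of the lists for high-light-inducible proteins and phycobilisome degradation, inorganic carbon uptake and ribosomal proteins rose, while most of those for photosystem I and the phycobilisome fell, as did chlL, chlN and chlB. The bicarbonate transporter gene cmpA (slr0040, forward strand, 3169882 to 3170406) was at least 35.31-fold higher (adjusted p = 7.04e-04), but its change was 9.52 and 10.18 on 2 slides and 2.64 on the slide of high light replicate 8. The gene hliA (ssl2542), for a small chlorophyll-binding stress protein, rose by 5.82 ± 0.16 (56.4-fold, adjusted p = 5.36e-11). The linker gene cpcG2 was at least 41.52-fold lower (adjusted p = 5.36e-11). In all, 788 of 3381 genes changed, of which 488 rose and 300 fell, and 41 of the rises were from and 23 of the falls to a level not well above background. At their bound 354 rises and 269 falls were at least 2-fold. The arrays of both groups did not overlap for 72.2% of genes, against 10% by chance.

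On the plasmid pSYSM, sll5043 was at least 48.91-fold higher (reverse strand, 41751 to 42199), sll5044 at least 41.32-fold, sll5041 at least 8.09-fold, sll5042 at least 47.04-fold and slr5053 at least 37.81-fold higher. The chromosomal gene ssr2016 was at least 31.8-fold higher. Large falls were those of chlL (slr0749, at least 28.62-fold lower) and chlN (slr0750, at least 17.51-fold lower), which encode subunits of the light-independent protochlorophyllide reductase. Others were those of the phycocyanin linker gene cpcC2 (sll1579, -5.34 ± 0.15), slr1634 (-5.05 ± 0.30) and slr0869 (at least 14.11-fold lower), both of unknown function, and the pSYSA genes sll7064 (at least 14.7-fold lower) and sll7065 (at least 10.6-fold lower). The light-repressed gene lrtA fell by 2.71 ± 0.12 on the log2 scale. Neither psbA2 (-0.18 ± 0.10) nor psbA3 (0.21 ± 0.10) passed the threshold, and the 5 psbA3 probes disagreed, with 1 at 1.47 and 4 between -0.20 and -0.06. Of these 4, 2 are cross-hybridising and lie at coordinates of psbA2 (7994 to 8052 and 8095 to 8153). The psbA2 probes themselves lay between -0.31 and -0.07. The psbA3 mean may therefore hold psbA2 signal, and whether psbA3 rose in high light stays open. The genes sigB (-0.51 ± 0.09), rbcL (0.29 ± 0.09) and hspA (0.92 ± 0.18) did not pass either, although hspA did without high light replicate 8 (1.08).

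In high light 16 of the 27 lists were called, 6 upward and 10 downward, of which 5 had means above 0 without scaling, and none was called with an estimated correlation. Of 53 ribosomal protein genes 51 rose and none fell (adjusted p = 4.63e-16, and adjusted p = 0.108 with an estimated correlation), led by rpl11 (sll1743, 2.33 ± 0.10), rpl19 (sll1740, 2.15 ± 0.15) and rps4 (slr0469, 2.13 ± 0.12). Of 12 photosystem I genes 11 fell (adjusted p = 7.92e-11, and adjusted p = 0.108 with an estimated correlation), among them psaK1 (ssr0390, -4.52 ± 0.20), psaJ (sml0008, -3.74 ± 0.10) and psaA (slr1834, -3.08 ± 0.22). Of 15 phycobilisome genes 12 fell (adjusted p = 6.02e-10, and adjusted p = 0.1869 with an estimated correlation), including cpcD (ssl3093, -4.61 ± 0.12) and the phycocyanin gene cpcB (sll1577, -3.96 ± 0.11). Of 25 photosystem II genes (mean -0.68, and 0.06 without scaling) 7 fell and none rose (adjusted p = 2.28e-07, and adjusted p = 0.1164 with an estimated correlation), with psbB (slr0906) at -1.61 ± 0.09 and psbO at -1.31 ± 0.13. All 7 high-light-inducible and phycobilisome degradation genes rose (adjusted p = 7.03e-04, and adjusted p = 0.1887 with an estimated correlation), including hliB (ssr2595, 5.41 ± 0.26) and hliC (ssl1633, 4.28 ± 0.13). Of 16 chlorophyll and tetrapyrrole genes 7 fell and 2 rose (adjusted p = 0.003965, and adjusted p = 0.2389 with an estimated correlation), with chlB (slr0772) at least 15.34-fold lower.

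In inducible inorganic carbon uptake 13 of 14 genes rose in high light and 1 fell (adjusted p = 0.003859, and adjusted p = 0.479 with an estimated correlation). Of these, sbtA rose by 5.46 ± 0.26 and cmpB (slr0041) was at least 26.81-fold higher, with a fitted change of 9.02 and 9.53 on 2 slides and 1.53 on the slide of high light replicate 8. The fall was that of the bicarbonate transporter gene bicA, named after its values were seen (-1.21 ± 0.38), which was not called without high light replicate 9 (-0.65) or when only the compared arrays were fitted. The mean of the carbon uptake list was 4.98 and 5.02 on 2 slides and 1.87 on the slide of high light replicate 8. The operon flv4, sll0218 and flv2, for flavodiiron proteins that take electrons from photosystem II and a partner protein, showed the same split. Bounds were 14.46-fold for flv4 and 5.87-fold for flv2, and fitted values were, for flv4 (sll0217), 6.86, 1.12 and 7.15 and for flv2 (sll0219) 5.26, 0.59 and 5.86 on slides 1 to 3, with replicate 8 on slide 2. The gene sll0218 was at least 12.15-fold higher, with 7.29, 1.37 and 7.73 on the same slides. These were the 3 of 5 flavodiiron genes that rose, and the list was not called (adjusted p = 0.5237), but was without high light replicate 8 (0.0118) and without scaling (4.36e-07), and its highest adjusted p was 0.8385. Of 13 NDH-1 core genes 9 rose, with ndhD2 (slr1291) at 2.99 ± 0.27, and ndhD1 (slr0331, named after its values were seen) fell (-1.01 ± 0.10) but was short of 2-fold without high light replicate 8 or 9 (-0.96 in both). That list was not called (adjusted p = 0.101), but was without high light replicate 8 (0.003539), without scaling (0.02985), with normexp (0.01302) and with the floor (0.03937), in a range of 0.003539 to 0.2049 over all alternatives. In carboxysome and RuBisCO 5 of 12 genes rose (adjusted p = 0.003965, and adjusted p = 0.3432 with an estimated correlation), with ccmN (sll1032) at 1.41 ± 0.11 and ccmK1 (sll1029) at 1.21 ± 0.11.

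The ATP synthase list was called upward in high light with 0 of 9 genes past the threshold (mean 0.62, adjusted p = 0.01321, and adjusted p = 0.2841 with an estimated correlation). Of 14 nitrogen assimilation genes 7 fell (adjusted p = 0.0149, and adjusted p = 0.4659 with an estimated correlation), among them glnN (slr0288, at least 6.31-fold lower), amt1 (sll0108, -1.91 ± 0.30) and glnA (-1.65 ± 0.32). On the slide of high light replicate 8 the list mean was -0.37 against -1.24 and -0.95. Of 5 bidirectional hydrogenase genes 4 fell (adjusted p = 0.002722, and adjusted p = 0.2584 with an estimated correlation), with hoxY (sll1224) at -1.46 ± 0.14. In sugar catabolism (mean -0.66, and 0.08 without scaling) 7 of 14 fell and 1 rose (adjusted p = 0.003965, and adjusted p = 0.1891 with an estimated correlation), with the glycogen phosphorylase gene glgP1 (sll1356) at least 5.86-fold lower. The rise was that of glgX1 (slr0237, at least 2.39-fold). Of 9 sigma factor genes (mean -0.48, and 0.26 without scaling) 2 fell, sigE (sll1689, at least 2.36-fold lower) and sigF (slr1564, -1.32 ± 0.10), and sigD (sll2012, 1.82 ± 0.21, named after its values were seen) rose (adjusted p = 0.003859, and adjusted p = 0.108 with an estimated correlation). Of 10 cytochrome b6f and electron carrier genes (mean -0.62, and 0.12 without scaling) 2 fell (adjusted p = 0.002207, and adjusted p = 0.1164 with an estimated correlation), petJ (sll1796, -2.12 ± 0.13) and petD (slr0343, -1.03 ± 0.10). The fall of petD did not pass without control replicate 1, where it was just short of 2-fold, or without high light replicate 8 (-0.97). Of 10 type IV pili genes (mean -0.43, and 0.30 without scaling) 2 fell (adjusted p = 0.04902, and adjusted p = 0.1887 with an estimated correlation), with pilT1 (slr0161) at -1.46 ± 0.10. That call was lost without control replicate 2 (0.05026), dark replicate 4 (0.05165) or 6 (0.05401), high light replicate 9 (0.1038) or CO2 depletion replicate 11 (0.05041) or 12 (0.05229). The range over all alternatives was 0.02939 to 0.1537.

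Of 8 phosphate uptake genes 4 rose in high light (adjusted p = 0.04902, and adjusted p = 0.4616 with an estimated correlation). Among them pstC1 (sll0681) was at least 3.23-fold higher. The phosphate call was lost with the slide as a block (0.05204), without control replicate 1 (0.05307), dark replicate 4 (0.05165) or 6 (0.05401), high light replicate 8 (0.06881) or CO2 depletion replicate 11 (0.05041) or 12 (0.05294). Over all alternatives its adjusted p lay between 0.02962 and 0.1059. Lists not called included chaperones and proteases, where 4 of 24 rose (groES, slr2075, 2.01 ± 0.14, and groEL1, slr2076, 1.72 ± 0.19), and oxidative stress defence, where 5 of 11 rose (gpx2, 3.21 ± 0.08, and ocp, 2.33 ± 0.15). Members that rose numbered 1 of 11 in Calvin cycle (tpi, slr0783, 1.48 ± 0.15) and 2 of 10 in circadian clock (kaiB1, slr0757, 1.51 ± 0.14, and rpaA, slr0115, 1.34 ± 0.12), with no fall. In respiratory oxidases 1 of 8 fell, cydA (slr1379, at least 1.93-fold lower, list mean -0.38, and 0.35 without scaling), and the list was called without high light replicate 7 (0.03159) or CO2 depletion replicate 10 (0.04547), against 0.06071 and a range of 0.03159 to 0.2522 over all alternatives. None of 6 iron genes passed, with a mean of -0.02, 0.72 without scaling, and a median of 0.07. Among 3 RNA helicase, RNA-binding and light-repressed genes 2 rose and lrtA fell, so that the mean was -0.22, and 0.51 without scaling, and the median 1.01. The rises were crhR (1.03 ± 0.16), short of 2-fold without high light replicate 7 or 9 (0.98 in both), and rbpA (sll0517, 1.01 ± 0.12), short of it without control replicate 3 (0.99) or high light replicate 7 (0.95) or 8 (0.91). Of 98 transposase genes 9 rose and 2 fell, ssr2227 among the falls (at least 2.52-fold lower). The transposase list was called with the slide as a block (0.02898), without control replicate 1 (0.04308), dark replicate 5 (0.04607) or high light replicate 8 (0.02811), against 0.06112 and a range of 0.007368 to 0.4462 over all alternatives. Of 314 plasmid genes 31 rose and 35 fell, with a mean of 0.04, -0.06 under quantile normalization, and a median of 0.01 while camera ranked the list downward and the rotation test fry upward. At their bound 18 of these rises and 30 of the falls were at least 2-fold, and the median of the flavodiiron list in high light moved from 3.91 to 2.55. Plasmid genes were called downward under quantile normalization (0.04632, against 0.09855), with normexp (0.03895), in the value table (0.04444) and with the floor (0.03691). Called upward with normexp and with the floor were the Calvin cycle (0.01859 and 0.03218, against 0.1691), chaperones and proteases (0.03357 and 0.03937, against 0.1691) and transposases (0.007368 and 0.03937). Oxidative stress defence was called upward with normexp (0.03242, against 0.1588) and the circadian clock with the floor (0.04349, against 0.4449).

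Rises and falls in high light numbered 1527 and 152 without scaling and 697 and 246 with scaling to spots above background on all arrays. The number of changed genes ranged from 301 in the deposited value table to 2251 with no minimum fold, and was 773 without high light replicate 8.

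The third comparison asked which transcripts changed when cells were held for 6 h without added inorganic carbon. Under CO2 depletion, the flavodiiron genes flv4 and flv2, the bicarbonate transporter genes cmpA, cmpB and sbtA and most genes of the NDH-1 core were higher. The bicarbonate transporter gene bicA and most genes of nitrogen assimilation, the phycobilisome, photosystem I and ATP synthase were lower. The flavodiiron gene flv4 (reverse strand, 166496 to 167149) was at least 96.77-fold higher (adjusted p = 1.03e-04), flv2 at least 32.14-fold and sll0218 between them at least 93.74-fold higher. The bicarbonate transporter genes cmpA and cmpB were at least 30.84-fold and at least 22.65-fold higher, and sbtA rose by 2.90 ± 0.26. Falls included those of cpcG2 (at least 21.37-fold lower, adjusted p = 8.85e-10), bicA (at least 11.09-fold lower) and the nitrate transporter gene nrtA (sll1450, at least 20.2-fold lower). In all, 484 of 3381 genes changed, of which 178 rose and 306 fell, and 12 of the rises were from and 38 of the falls to a level not well above background. At their bound 136 rises and 233 falls were at least 2-fold. The arrays of both groups did not overlap for 72.6% of genes, against 10% by chance.

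Other large rises under CO2 depletion were those of slr0616 (at least 20.06-fold higher), sll0788 (at least 6.18-fold higher, with 2 cross-hybridising probes) and gifA (3.99 ± 0.40). Large falls were those of narB (sll1454, nitrate reductase, at least 8.57-fold lower), amt1 (-4.47 ± 0.30), amiC (slr0447, annotated as an amidase regulator, -4.33 ± 0.28), nrtB (at least 17.8-fold lower), nirA (at least 14.81-fold lower) and glnA (-4.00 ± 0.32). Photosystem I gene psaA fell by 1.01 ± 0.22 on the log2 scale and was short of 2-fold without control replicate 1 (-0.94). The gene lrtA fell by 1.32 ± 0.12 on the log2 scale. Values that did not pass were those of psbA2 (0.33 ± 0.10), psbA3 (0.49 ± 0.10), rbcL (0.07 ± 0.09), sigB (0.28 ± 0.09) and hspA (0.88 ± 0.18). The gene isiA, also fixed in advance, was not well above background on all arrays of any group and was not tested in any comparison.

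Under CO2 depletion 14 lists were called, 5 upward and 9 downward, and again none with an estimated correlation. Of 15 phycobilisome genes 13 fell (adjusted p = 1.66e-10, and adjusted p = 0.1398 with an estimated correlation), including cpcC2 (-4.03 ± 0.15) and cpcB (-3.21 ± 0.11). All 9 ATP synthase genes fell (adjusted p = 1.86e-08, and adjusted p = 0.08669 with an estimated correlation), led by atpC (sll1327, -2.38 ± 0.08) and atpA (sll1326, -2.24 ± 0.08). All 12 photosystem I genes fell (adjusted p = 2.22e-08, and adjusted p = 0.08669 with an estimated correlation), led by psaK1 (-2.68 ± 0.20) and psaL (slr1655, -2.38 ± 0.13). Of 53 ribosomal protein genes 12 fell and none rose (adjusted p = 1.86e-08, and adjusted p = 0.1784 with an estimated correlation), with rps10 (sll1101) at -1.32 ± 0.11. Of 16 chlorophyll and tetrapyrrole genes 9 fell (adjusted p = 4.21e-07, and adjusted p = 0.08669 with an estimated correlation), with chlN at least 8.91-fold lower and por (slr0506), the light-dependent protochlorophyllide reductase gene, at least 7.6-fold lower. Of 25 photosystem II genes 12 fell and 1 rose (adjusted p = 2.05e-06, and adjusted p = 0.1398 with an estimated correlation), with psbO at -2.70 ± 0.13 and psbV (sll0258) at -1.71 ± 0.08. The rise was psbA1 (slr1181, at least 1.78-fold), another D1 gene, named after its values were seen. Of 14 nitrogen assimilation genes 11 fell and 2 rose (adjusted p = 9.58e-05, and adjusted p = 0.2485 with an estimated correlation), and the rises were again gifA and gifB (2.86 ± 0.11, the latter named after its values were seen).

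Of 10 cytochrome b6f and electron carrier genes 5 fell under CO2 depletion (adjusted p = 1.84e-04, and adjusted p = 0.08669 with an estimated correlation), with petJ at least 5.52-fold lower and petA at -1.55 ± 0.10. Of 13 NDH-1 core genes 9 rose (adjusted p = 1.87e-04, and adjusted p = 0.4598 with an estimated correlation), including ndhD2 (2.27 ± 0.27) and ndhC (slr1279, 2.04 ± 0.20). Of 7 high-light-inducible and phycobilisome degradation genes 6 rose (adjusted p = 8.28e-04, and adjusted p = 0.2043 with an estimated correlation), with hliC at 2.70 ± 0.13 and hliA at 1.58 ± 0.16. Of 11 Calvin cycle genes 4 fell (adjusted p = 0.004024, and adjusted p = 0.2344 with an estimated correlation), with rpiA (slr0194) at least 2.97-fold lower. In inducible inorganic carbon uptake 11 of 14 rose and bicA fell (adjusted p = 0.005665, and adjusted p = 0.6398 with an estimated correlation). Of 5 flavodiiron genes 4 rose (adjusted p = 0.03023, and adjusted p = 0.5512 with an estimated correlation). Slide means were 2.29, 2.66 and 2.44 for carbon uptake and 4.86, 4.92 and 4.71 for flavodiiron proteins. The estimated correlations of both lists (0.67 and 0.825) were the same in every comparison. These correlations, and the variances behind the p-values, were taken over all 12 arrays, high light replicate 8 among them. Of 9 sigma factor genes sigH (1.65 ± 0.08) and sigD (1.06 ± 0.21, named after its values were seen) rose and sigE fell, at least 2.68-fold (adjusted p = 0.03023, and adjusted p = 0.1398 with an estimated correlation). Lists not called had 1 fall of 12 in carboxysome and RuBisCO (ccmM, -1.22 ± 0.12), 2 of 14 in sugar catabolism (glgX2, slr1857, at least 2.51-fold lower, and gap1, slr0884, at least 1.56-fold lower) and 4 of 24 in chaperones and proteases (htpG, sll0430, at least 2.66-fold lower, and groES, -1.37 ± 0.14). They also had 3 falls of 8 in phosphate uptake (pstS1, sll0680, -1.21 ± 0.18, and pstC1, too dim for a fold) and 2 of 10 in circadian clock (kaiB2, sll1596, at least 1.65-fold lower). At bounds the median of the phosphate list moved from -0.39 to 0.00, with 1 fall of at least 2-fold, and 0 of the clock falls were of that size. Short of 2-fold was the fitted change of pstC1 without control replicate 1 (-0.90) or CO2 depletion replicate 10 (-0.98). The iron acquisition and storage list had 1 fall of 6 (futA1, slr1295, at least 2.27-fold lower), and 1 of 3 fell, lrtA, among RNA helicase, RNA-binding and light-repressed genes. Oxidative stress defence had 1 rise and 1 fall among 11 genes, the fall that of frp (slr1964, -2.10 ± 0.20) and the rise that of gpx1 (slr1171, 1.01 ± 0.09), which was short of 2-fold without control replicate 1 (0.96) or CO2 depletion replicate 11 (0.97). Of 314 plasmid genes 8 rose and 22 fell, among them slr6039 (at least 5.21-fold higher) and the pSYSA gene sll7086 (at least 7.99-fold lower). No member passed in bidirectional hydrogenase (0 of 5), respiratory oxidases (0 of 8), type IV pili (0 of 10) or transposases (0 of 98). The mean and median differed in sign in the circadian clock (-0.10, which was 0.07 in the deposited value table, and 0.09), iron (-0.16 and 0.03) and plasmid (-0.04 and 0.07) lists. Camera ranked the clock, plasmid and respiratory oxidase lists upward, and fry ranked the plasmid and oxidase lists downward.

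The number of genes changed under CO2 depletion ranged from 152 in the deposited value table to 1935 with no minimum fold. In that last setting 997 rose and 938 fell, so that the excess of falls seen at 2-fold was not kept. The carbon uptake call was lost in the deposited value table (adjusted p = 0.05958, with a lowest value of 8.83e-24 over all alternatives) and the sigma factor call without scaling (0.3192, with a lowest value of 0.02322).

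**Figure D1:**
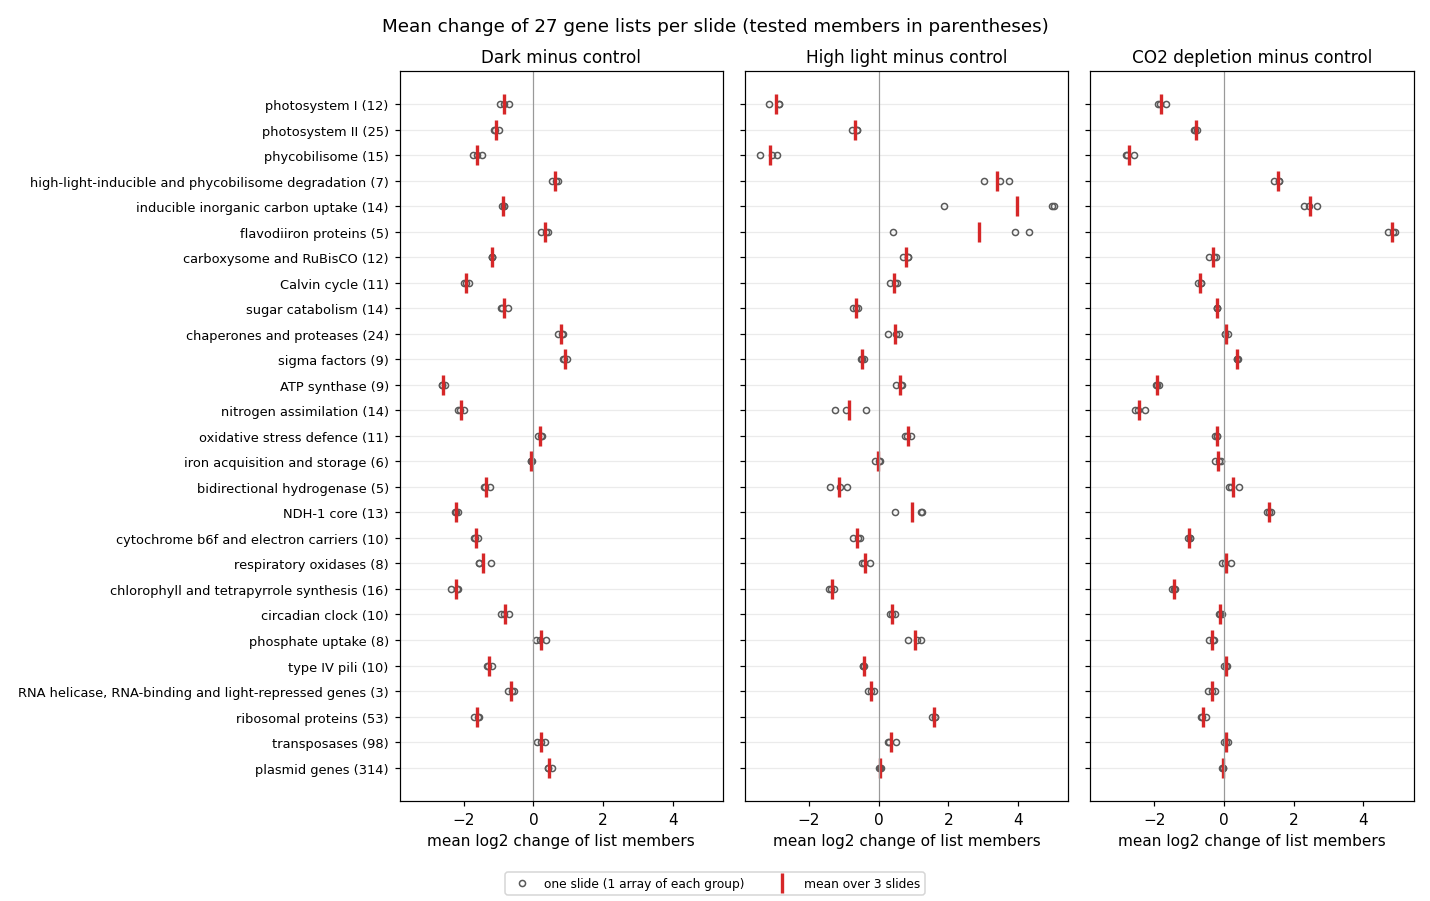
Mean log2 change of the tested members of each of 27 gene lists against the control (x axis, log2) in the dark, in high light and under CO2 depletion, with lists on the y axis and their number of tested members in parentheses. Circles are the 3 slides, each of which held 1 array of every group, and red bars are their means. In high light the slide of replicate 8 lies apart for inducible inorganic carbon uptake (1.87 against 4.98 and 5.02) and flavodiiron proteins (0.41 against 3.92 and 4.32), list means above 0 in the dark panel fell below 0 without scaling, and some means below 0 in the high light panel, such as photosystem II, rose above 0.

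High light and darkness were also compared directly. Between them hspA, sigB and lrtA were lower in high light and sbtA, cmpA, hliA and rbcL were higher. The gene hspA differed by -8.70 ± 0.18 (adjusted p = 6.90e-13), sigB by -3.78 ± 0.09 and lrtA by -4.70 ± 0.12. The gene sbtA was at least 88.36-fold higher in high light and hliA at least 33.32-fold, and rbcL was higher by 2.55 ± 0.09. There cmpA was at least 11.89-fold higher, with a change of 0.99 on the slide of high light replicate 8 and 7.82 and 8.38 on the others. The genes psaA (-3.76 ± 0.22) and cpcB (-3.16 ± 0.11) were lower in high light, as was psbA2 (-1.20 ± 0.10), which turned to 0.80 without scaling and 0.66 under quantile normalization. The gene psbA3 (-0.81 ± 0.10) did not pass and also turned upward without scaling, which moves all genes alike. The gene flv4 was at least 5.47-fold higher, with 0.22 on the slide of high light replicate 8. The gene glnA was higher (1.02 ± 0.32), but not past the threshold without dark replicate 4 (0.97) or high light replicate 8 (0.56). In all, 1681 genes differed, 1089 higher in high light and 592 higher in the dark, and 479 of the former were not well above background in the dark. Of the latter, 56 were not well above background on all dark arrays. At their bound 500 and 422 were at least 2-fold. These counts were 2786 and 100 without scaling, 1611 and 324 with scaling to spots above background on all arrays and 492 and 653 with normexp background correction, and the total was 556 in the deposited value table.

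**Figure D2:**
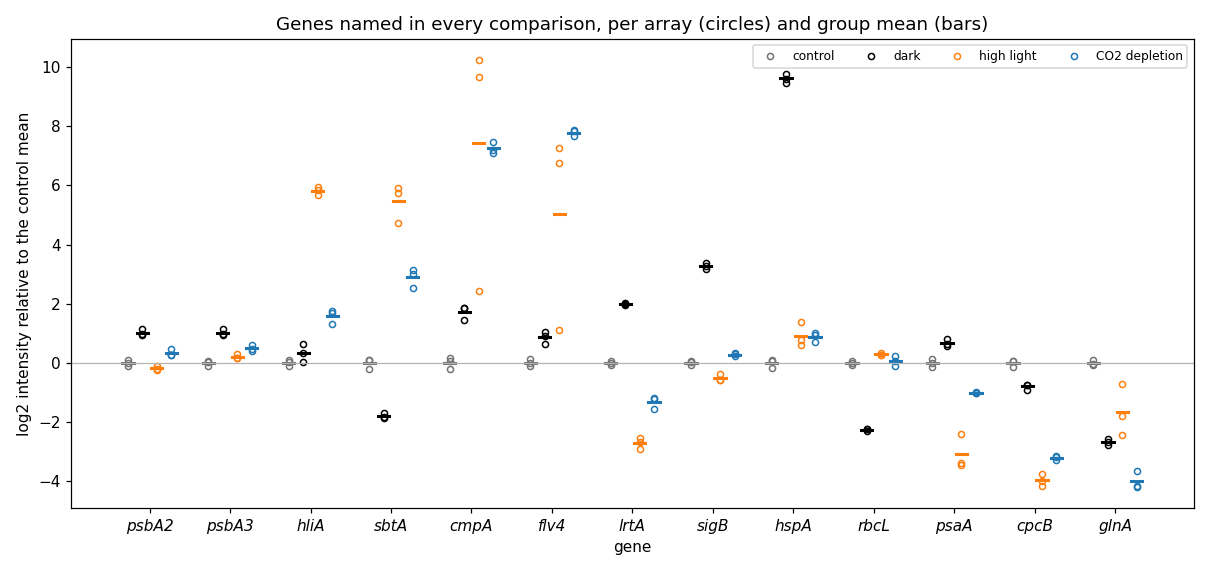
Log2 intensity, relative to the mean of the control arrays (y axis), of the 13 tested genes that were named in every comparison (x axis), with each array as a circle and the group mean as a bar. The gene hspA stands at 9.62 in the dark, high light replicate 8 lies below the other high light arrays for cmpA and flv4, and cmpA and sbtA rose in high light and under CO2 depletion, while psbA2 and psbA3, at 1.02 in the dark, turned to -0.24 without scaling.

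Antisense and intergenic features were tested as separate classes. In the dark most antisense features that changed were higher relative to the scaling, and in high light most were lower. Of 780 antisense features tested, 299 changed in the dark (241 rose and 58 fell), 187 in high light (40 and 147) and 69 under CO2 depletion (21 and 48). Large rises in the dark were those of 2 segments opposite the gene of phosphoribosyl aminoimidazole carboxylase, genome_4951 (forward strand, 3536679 to 3536725, at least 19.94-fold higher) and genome_4952 (3536960 to 3537005, 2.72 ± 0.11), and of genome_4413 (3116358 to 3116529, 3.34 ± 0.15). The segment genome_3802, opposite a penicillin-binding protein gene (reverse strand, 2675842 to 2676098), was at least 3.28-fold lower in the dark and at least 7.93-fold lower under CO2 depletion. In high light genome_2959 was at least 21.21-fold lower (forward strand, 2047365 to 2047508), and genome_297, opposite a carboxysome gene (forward strand, 218856 to 218973), at least 9.49-fold lower. The segment genome_1024, opposite cpcC2 (forward strand, 725947 to 726004), was at least 10.72-fold higher in high light and at least 4.44-fold higher under CO2 depletion, where genome_4569 (3235788 to 3236276) also rose, by 3.05 ± 0.17. Of the 241 rises in the dark, 34 were of features not well above background on all dark arrays. Rises and falls of antisense features depended on the scaling, with 8 and 285 in the dark and 112 and 31 in high light without scaling. They were 96 and 114 and 56 and 92 in the same order with scaling to spots above background on all arrays, 151 and 13 in the dark with normexp background correction and 2 and 10 under CO2 depletion in the deposited value table.

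Of 635 intergenic features tested, 290 changed in the dark (193 rose and 97 fell), 179 in high light (45 and 134) and 88 under CO2 depletion (27 and 61). The segment genome_890 (reverse strand, 631778 to 631837), beside gifA on the same strand, rose by 4.05 ± 0.36 in the dark and by 4.03 ± 0.36 under CO2 depletion. In the dark genome_665 (forward strand, 470935 to 470994) rose by 4.11 ± 0.14 and genome_416 (reverse strand, 298784 to 299079) by 4.09 ± 0.34, while genome_1701 (forward strand, 1190723 to 1190782) was at least 13.55-fold lower. In high light the pSYSM segment pSYSM_79 rose by 4.82 ± 0.15 (reverse strand, 57844 to 57903), and genome_1637, beside hliC on the same strand (reverse strand, 1141695 to 1141754), rose by 3.89 ± 0.12. The segment genome_3361 (forward strand, 2347342 to 2347401) fell in high light (-4.33 ± 0.26) and was at least 22.4-fold lower under CO2 depletion. Under CO2 depletion genome_3034 (forward strand, 2098675 to 2098855) fell by 3.82 ± 0.14 on the log2 scale, and genome_741, beside glnA on the same strand (forward strand, 532980 to 533039), fell by 3.79 ± 0.27 on the log2 scale. Of the rises in the dark, 10 were of features saturated in a compared group and 17 of features not well above background on all dark arrays. Of these 10, 3 were saturated in both groups, where the signal can show no rise. Their calls come from the scaling, since the 75th percentile stood at -1.26 (log2) in the dark against the control. Rises and falls were 14 and 281 in the dark and 117 and 42 in high light without scaling. They were 77 and 151 and 59 and 89 in the same order with scaling to spots above background on all arrays, 105 and 97 in the dark and 34 and 47 under CO2 depletion with quantile normalization, and 33 and 39 in the dark in the deposited value table.

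Whether a gene and the RNA opposite to it changed in the same or in opposite directions was compared over 754 pairs, which are not independent replicates since some genes have several segments. Opposite fitted changes, picked after their values were seen, included those of the ribosomal protein gene rpl3 (sll1799, 1.95, and -2.10 for its antisense segment) in high light and of the cell division gene ftsZ (sll1633, -2.51, and 1.67) in the dark. Another was flv4 (7.78, and -1.34) under CO2 depletion, where the antisense segment lies at 167559 to 167657 on the forward strand. Across pairs, Spearman's rho of both changes was -0.033 in the dark (permutation p = 0.3578, adjusted p = 0.3578), -0.055 in high light (permutation p = 0.133, adjusted p = 0.1995) and -0.097 under CO2 depletion (permutation p = 0.0083, adjusted p = 0.0249), with Pearson's r at -0.042, -0.14 and -0.131. Within slides rho was between -0.039 and -0.028 in the dark, between -0.092 and -0.035 in high light and between -0.118 and -0.064 under CO2 depletion. Both members changed in 103, 54 and 7 pairs, of which 58, 37 and 4 went in opposite directions, against 63.9, 22.0 and 3.5 for independent lists. In Fisher's exact test, 2-sided, no association between the directions of both members was shown (p = 0.5946, 0.1616 and 1, and adjusted p = 0.8919, 0.4848 and 1).

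Genes shared between the comparisons were counted for each direction. Genes that fell under both darkness and CO2 depletion numbered 225, those that fell in both high light and CO2 depletion 133 and those that fell in both darkness and high light 155, and 102 genes fell in all 3, among them cpcG2, bicA, psbO, nrtA and nrtB, picked after their values were seen. Rises numbered 51, 66 and 61 in the same order, and 15 genes rose in all 3, including sll0788, also picked after its values were seen. Independent lists of the same size would share 79.5, 27.2 and 77.9 falls and 30.1, 25.7 and 82.4 rises. Groups simulated without any change against the same controls shared at most 1 gene. That simulation cannot show how far shared controls raise the overlap, because groups without change have hardly any calls to share. In the simulated test of the pipeline 0 or 1 of 3181 unchanged genes were called. Opposite directions were seen for 43 genes between darkness and CO2 depletion, for 50 between high light and CO2 depletion and for 199 between darkness and high light, against 97.9, 60 and 177.4 for independent lists. The 3 control arrays are too few to be split between the comparisons, and part of any excess may come from these shared controls. In 1469 genes none of the 3 comparisons passed.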

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

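The tests of signal of fixed size, of the bright control spots and of rRNA labelling were chosen only after the results they measure were seen. The same holds for the comparisons of CRISPR probes and for the scaling to spots above background on all arrays. Predictions for the other tests in this part were written before those tests were run. Those on the antisense rise and on high light replicate 8 concern patterns that had already been seen.

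The 138 probes against CRISPR arrays were in none of the comparisons and were looked at because they gave signal outside them. Of 110 probes tested, 46 rose past the threshold in the dark and 2 fell (limma, 84 of 110 at an unadjusted p under 0.05 in either direction). In high light 65 fell past it and 0 rose (103 at an unadjusted p under 0.05). Changes in high light ran from -4.11 to -0.23, all on the side below the control. Under CO2 depletion 21 probes fell past the threshold and 0 rose (42 at an unadjusted p under 0.05). Their median changes were 0.94, -1.06 and -0.21 relative to the scaling of each array, and -0.31, -0.33 and -0.16 without scaling, where 1 rose and 20 fell in the dark, 16 fell in high light and 19 under CO2 depletion.

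The antisense features that changed in the dark mostly rose relative to the scaling (241 of 299). Without scaling 8 rose and 285 fell, with scaling to spots above background on all arrays 96 rose and 114 fell, and under quantile normalization 242 and 47. These counts do not show scaling as the cause, since another constant per array moves all features alike. The median change of antisense features was 0.57, and the median over averages of 5 genes of like control level was -0.28. The difference of these medians, 0.85 (bootstrap 95% interval 0.76 to 0.96), was planned as the test of scaling and met the bound set against it. It sets single features against averages of genes. That bound was wrong by design, since 1 constant per array cannot alter this difference (0.85 without scaling as well), so that scaling cannot be told apart from a rise. Their unscaled median was -0.68 (-0.59, -0.66 and -0.75 on the 3 slides), against -1.35 for genes. A part of the signal that is of fixed size, such as labelled DNA, cannot be told apart from a smaller loss of antisense RNA than of messages, because both lead to a smaller unscaled fall than that of genes. All of these stay open. A biological cause by darkness was not tested separately.

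The unscaled signal was lower on dark arrays (75th percentile -1.26 against the control, log2). Weaker hybridisation or scanning would have dimmed the bright-corner control spots, which bind an added labelled oligonucleotide, but these lay 0.25 higher on average (0.37, 0.37 and 0 on the 3 slides). Whether these spots were saturated was not checked, and saturation could hide a dimming. Weaker labelling of dark RNA cannot be told apart from a lower share of mRNA, because only 7 rRNA probes were above background and not saturated, and their median was -0.29 (-0.36, -0.34 and -0.41 on the 3 slides) with a range from -1.73 to 0.03. The same probes stood at 1.93 in high light, so that they are no steady reference. A lower share of mRNA in darkness stays open and was not tested.

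High light replicate 8 had a weaker response of the inorganic carbon uptake and flavodiiron lists than replicates 7 and 9 (1.83 against 4.96 and 5.08, and 0.37 against 3.95 and 4.33, relative to the control mean). Slide means of the NDH-1 core (0.48 against 1.23 and 1.21) and nitrogen assimilation (-0.37 against -1.24 and -0.95) were weaker there too. Those of photosystem I (-2.86 against -3.15 and -2.85) and ribosomal proteins (1.63 against 1.62 and 1.54) were not. Compressed differences on that array would have lowered other genes as well, but the median ratio of its changes to those of the other replicates was 1.04 over 771 genes outside the lists, against 0.16 over 17 genes inside them. A slide effect would have lowered both lists on that slide in the other groups, but the lowest of the 3 differences was -0.05. A label swapped with another group does not account for it either, since its highest correlation with an array of another group was 0.83, and its lowest with the other high light arrays 0.959. A candidate explanation is less inorganic carbon limitation in that sample, for which a negative relation was predicted between its difference from the other high light arrays and the CO2 depletion change of each gene outside the lists. Spearman's rho across genes was -0.269 (-0.305 to -0.234, 2591 genes, which are not independent replicates), and -0.279 given the control level. This is a hypothesis, and inorganic carbon was not analysed here.

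Each comparison of 3 against 3 arrays has 10 splits, too few for a share under 0.05. In a fit of only the 6 arrays compared, 1 of 10 splits, the real one, gave as many changed genes in the dark (1457), in high light (785), under CO2 depletion (486) and between high light and dark (1678), with 0 in the highest other split. The same held for antisense features (299, 186 and 70, highest other 0) and intergenic features (292, 179 and 89, highest other 0). For gene lists 4 of 10 splits gave as many in the dark (real 11, highest other 13), 2 in high light (16 and 16) and 3 under CO2 depletion (14 and 15). The number of lists called at the preset correlation therefore does not set the real groups apart from other splits.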

How the results depend on the processing

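Scaling to spots above background on all arrays, the common floor, leaving out cross-hybridising probes the limit to calls above background in the brighter group and the limit to calls of 2-fold at their bound were chosen after seeing the data. Of the counts and correlations under all alternatives, 348 stayed within 1.5 times the count or within the replicate spread and 78 did not. Of the values of all genes and segments that the naming rule gives or the text names, 7026 kept direction and side of the threshold, 262 fell short of it, 27 newly passed and 13 reversed. Of 307 calls among them, 25 were under 2-fold at their bound. The cause was not tested except where the construction shows it.

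With no minimum fold, more passed by construction: 2783 genes, 590 antisense and 523 intergenic features in the dark, 2251, 558 and 475 in high light, 1935, 325 and 296 under CO2 depletion and 2825 genes between high light and dark. With normexp background correction 697 genes, 164 antisense and 140 intergenic features changed in the dark, 475 genes and 104 antisense features in high light, and 262, 26 and 54 under CO2 depletion. Shared genes were then 103 between dark and high light and 138 between dark and CO2 depletion. In the deposited value table the counts were 403, 38 and 72 in the dark, 301, 38 and 93 in high light, 152, 12 and 36 under CO2 depletion and 556 between high light and dark, with 76, 88 and 81 shared genes. That table apparently holds signal without background subtraction, which narrows folds, so that these counts do not measure normalization alone. Without scaling 1679 genes changed in high light and 2886 between high light and dark. Without a filter 533 antisense and 509 intergenic features changed in the dark, as more were tested. With a probe above background on all 12 arrays, where fewer were tested, 952 genes changed in the dark, 493 genes and 105 antisense features in high light, 321 and 34 under CO2 depletion and 1114 genes between high light and dark, with 125, 173 and 125 shared genes. With the common floor the counts were 569 genes and 147 antisense features in the dark, 396 and 78 in high light, 249 and 26 with 58 intergenic features under CO2 depletion and 738 between high light and dark, with 99, 145 and 126 shared genes. Limited to calls of 2-fold at their bound, 675 genes changed in the dark and 922 between high light and dark, with 113 genes shared between dark and high light and 168 between dark and CO2 depletion.

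The correlation of sense and antisense changes in the dark was -0.052 under quantile normalization and normexp, -0.062 in the value table, -0.049 without a filter, 0.006 with a probe above background on all 12 arrays, -0.017 for the median over probes, -0.042 with the floor or as Pearson's r and 0.036 over changed pairs. In high light it was -0.139 with a probe above background on all 12 arrays and -0.14 as Pearson's r, and under CO2 depletion -0.131 as Pearson's r and -0.199 over changed pairs. With an estimated correlation 0 lists were called in each comparison, and fry called 25 in the dark. List calls lost in high light without scaling were carboxysome (adjusted p = 0.1077), sigma factors (0.1517), ATP synthase (0.2979), cytochrome b6f (0.06221), phosphate (0.06035) and type IV pili (0.1537). The pili call was also lost under quantile normalization (0.07327), normexp (0.1117), the value table (0.08164) and the floor (0.1459), the phosphate call with the floor (0.1059) and with scaling to spots above background on all arrays (0.06307), and the nitrogen call with normexp (0.05874) and the floor (0.05305). In the dark the nitrogen call was lost with scaling to spots above background on all arrays (0.1077) and the respiratory oxidase call with the floor (0.1519). The D1 gene psbA2 reversed in the dark under quantile normalization (-0.07), without scaling (-0.24) and in the value table (-0.07), and psbA3 without scaling (-0.24). Between high light and dark psbA2 reversed in the same settings (0.66, 0.80 and 0.66). Without scaling sodB (-0.02), futA2 (-0.10), phoA (-0.14) and nucH (-0.18) reversed in the dark. With the common floor genome_1155 in high light and genome_3853 under CO2 depletion stood at 0, since both groups were set to the floor.

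Leaving out 1 array at a time gave 1430 to 1466 genes, 289 to 317 antisense and 278 to 293 intergenic features and 11 to 12 lists in the dark. It gave 773 to 871, 169 to 233, 169 to 209 and 15 to 18 in high light, and 468 to 499, 66 to 75, 76 to 91 and 14 to 14 under CO2 depletion. Between high light and dark 1647 to 1721 genes differed, and shared genes numbered 211 to 231, 270 to 283 and 193 to 211. The correlations ranged from -0.035 to -0.03, -0.064 to -0.038 and -0.122 to -0.081. Signal over background limits comparisons with the dark arrays, where 390 falls from the control and 479 rises to high light have a dark level not well above it.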

Other observations

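No test in this part was chosen before the values were seen. Several intergenic segments that changed lie next to genes on the same strand that changed in the same direction. The segment genome_890 beside gifA rose in the dark (4.05) and under CO2 depletion (4.03), genome_1637 beside hliC rose in high light (3.89) and under CO2 depletion (2.43), and genome_741 beside glnA fell under CO2 depletion (-3.79). No transcript ends were measured, and whether these segments belong to the transcripts of their neighbours was not tested.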
